A study of Drosophila melanogaster with 3 samples.

How the data were processed

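Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out with an anti-GFP antibody on whole embryos of Drosophila melanogaster, collected from 0 to 24 hours of age and of both sexes. The antibody label reads pnt while the description says anti-GFP, and the description was followed here. The flies carried an eGFP exon inserted in an intron of pnt, so that the gene makes a Pointed-eGFP fusion protein. Pointed is an ETS-domain transcription factor that acts downstream of the EGF receptor and the MAP kinase cascade. Chromatin was sonicated to fragments of 200 to 800 bp, per the labels. The labels give 1 group of 3 biological replicates and no second condition, so the comparisons made are between replicates, between peaks and randomly placed or matched sequence, between gene lists and random genes, and between 2 genome builds.

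The deposited files used were peak lists in narrowPeak form on builds dm6 and dm3. For each build there was a relaxed list for each replicate, a relaxed list from the pooled replicates and an optimal list. The relaxed lists hold both strong peaks and background regions, as input for the irreproducible discovery rate (IDR) procedure. Per the file notes deposited with the samples, each replicate's list was called from its own alignment against a control, the pooled list from the 3 alignments and that control, and the optimal list was derived from the relaxed lists. The aligner, the peak caller, their versions and the IDR threshold are not given in the sources used here. The authors gave each peak a signal value, whose scale is not stated in the sources used here, and it was used to rank and describe peaks within a list. Values of different lists are given as deposited, their scales may differ, and no test compares them. The authors gave the significance of each peak as −log10 of a q-value. Another deposited column places the summit within the peak. In 80.9% of the optimal peaks that summit was the midpoint of the peak, which limits how finely summits place the bound sequence. Signal tracks and read alignments were not analysed here. The read depth of each library and of the control is therefore unknown, and intervals given for shares of peaks cover counting error only.

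All sequence and annotation work was done on dm6, which matches the reference used here (Release 6 sequence with the Ensembl release 115 annotation, FlyBase release 6.54). Coordinates are 1-based dm6 positions. The dm3 lists were compared by counts and shares only, and no coordinates were converted. The arms X, 2L, 2R, 3L, 3R and 4 were analysed.

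For comparison between replicates, each replicate's own 3646 peaks of highest signal were taken, as many as the optimal list holds. These are called the replicate's top list below. An optimal peak counted as overlapped when at least 1 bp was shared, and the chance level came from 100 shuffles of the replicate peaks within their chromosome. Spearman's rho was computed across optimal peaks matched in both replicates of a pair. Peaks are not independent replicates, so no test was made of rho. Each summit was assigned to 1 of 7 classes in a fixed order of precedence, beginning with TSS-proximal, which means within 500 bp of an annotated transcription start site (TSS). Class shares were set against 1000 random placements on the same arm, with a two-sided permutation p. The share of peaks on each of the 6 arms was set against its share of sequence other than N by an exact binomial test.

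For sequence patterns, windows reaching 100 bp either side of the summit were searched on both strands for 17 consensus patterns. Each peak was matched with 1 background window of the same arm, class and GC bin (width 0.02), over 1000 bp from any summit of the pooled list, and the shares were compared by a two-sided Fisher's exact test. One of the patterns is the ETS pattern reversed without complementing, as a control of like composition. For gene lists, a protein-coding gene was called bound when an optimal summit lay in its span or within 2 kb. The number of bound members was set against 10000 random lists matched on gene span in 20 bins, with a two-sided permutation p. The p-values of these tests were adjusted by the Benjamini-Hochberg method within their family of 7 classes, 6 arms, 17 patterns or 19 lists, with a threshold of 0.05. The permutation p for ETS match against peak signal was not adjusted. Tests of short words, given at the end, were adjusted over 2080 words, or over the 10 leading ones on the arms not used to choose them. Intervals on shares are 95% Clopper-Pearson intervals. Values over replicates are mean ± SD over the 3 top lists, which reuse the libraries behind the optimal list and are not independent of it.

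The design, the patterns, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The named genes are pnt, the genes with the TSS nearest to the 10 strongest optimal peaks, the 10 protein-coding genes with the most optimal summits, and, in each list, the 3 bound members with the strongest peak and up to 3 members without a peak in alphabetical order. A gene that this rule names is not reported here. Some lists were defined by a pattern of gene symbols. The one for eggshell and yolk proteins also took in Cp190, a chromatin insulator protein, and Cp110, a centriole protein. The one for male accessory gland proteins also took in Acp1 and Acp65Aa, which encode adult cuticle proteins. Several genes stand in more than 1 list. For the FGF, Notch and segmentation lists, 17 of 18 named members were matched to the annotation.

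The alternatives were a 50% reciprocal overlap, summits within 100 bp, complete relaxed lists, the 1823 stronger peaks, TSS windows of 200 and 1000 bp, peak midpoints, pattern windows of 50 and 250 bp, background windows 2 kb to the right, other ways to assign peaks to genes, Fisher's exact test without matching on span, and leaving out each replicate. Alternatives chosen after seeing the data were 10 background windows per peak, weaker pooled peaks as background, windows of 500 bp, TSS-proximal and other peaks taken apart, and only those peaks overlapped in the top lists of all 3 replicates.

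The scripts used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. The code was tested on simulated data. Uniformly placed summits gave a TSS-proximal fold of 1.02 with 0 of 7 classes past the threshold. An ETS match planted in 10% of 3646 background windows was found in every planted window, at an odds ratio of 2.44. This checks the search code and not its power at peaks. Between 2 background draws 0 of 17 patterns differed. Random lists of 18 genes gave an unadjusted permutation p under 0.05 in 2.75% of 400 draws.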

Results

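Binding of the Pointed-eGFP fusion protein was measured by anti-GFP ChIP-seq in whole embryos, in 1 group of 3 biological replicates. The optimal list on dm6 held 3646 peaks. Their signal ran from 93.2 to 2989 with a median of 153.5, in the authors' units. They were exactly the 3646 peaks of highest signal among the 23148 of the pooled relaxed list. Each replicate's relaxed list held 30000 peaks. The number of reads behind each list is unknown, so a gene without a peak is one without a listed peak at this unknown depth, and not one shown to be unbound.

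The strongest peaks lay at genes of varied function, and most of them were at promoters. The strongest of all (3L:19590433-19590804, signal 2989) lay 98 bp from the TSS of CG14100 and ranked 1, 2 and 2 in the lists of replicates 1, 2 and 3. The next (2L:480877-481289, signal 2973) was intronic, 1408 bp from the TSS of cbt, a zinc finger transcription factor gene, and inside the overlapping gene ush. It ranked 3, 1 and 1. The third was 36 bp from the TSS of Ugalt, a UDP-galactose transporter gene (X:2703704-2704069, signal 2647). The fourth was TSS-proximal at ph-p, which encodes a Polycomb group protein (X:2137174-2137564, signal 2296). The fifth lay in an intron of the kinase gene Lk6 (3R:11760870-11761243, signal 2104). The others of the 10 strongest were nearest to Chro, Art3, CG11050, CG1888 and mRpL41, with signals from 1700 to 1951, and all but that at CG11050 were TSS-proximal. All 10 stood among the 24 highest-ranked peaks of every replicate.

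The pnt gene itself (3R:23290231-23346167) held 2 optimal peaks. The stronger lay in an intron (3R:23326414-23326595, signal 373, rank 375 of 3646), 7284 bp from the nearest TSS, and ranked 381, 519 and 437 in the 3 replicates. The genes with the most summits in their span or within 2 kb were CG1677 and kirre with 15 each, shn with 14 and Raf with 13. CHES-1-like, Hr4, sbb and ush had 11 each, and Ptp61F and jing had 8 each. Raf encodes the MAP kinase kinase kinase of the pathway upstream of Pointed, and its strongest peak (X:2297550-2297863, signal 1079) was intronic and ranked 36. Most of these genes are long, with 394149 bp for kirre and 124709 bp for CG1677. Several contain other genes, so that the strongest peak within CG1677 was TSS-proximal at CBP and that within Ptp61F was nearest to SA2.

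The first comparison asks how far the replicates gave the same peaks. Of the optimal peaks, 2078 (57.0%) were overlapped in the top lists of all 3 replicates, 1027 in those of 2, 519 in that of 1 and 22 in none. Those found in all 3 had a median signal of 217.6, against 101.9 for those found in 1. The top list of replicate 1 overlapped 86.6% of the optimal peaks (95% interval 85.4 to 87.7), that of replicate 2 81.5% (80.2 to 82.8) and that of replicate 3 73.4% (72.0 to 74.9). The mean was 80.5% ± 6.64 (SD, n = 3), and shuffled peaks gave 1.92%. The optimal list draws on these same libraries, so an overlap above that of shuffled peaks says little about agreement between replicates. Replicates 1 and 2 shared 78.2% of their top lists, replicates 1 and 3 65.8%, and replicates 2 and 3 60.2%. Spearman's rho of signal across matched optimal peaks was 0.806, 0.573 and 0.533 for the same pairs, with a mean of 0.637 ± 0.147 (SD, n = 3 pairs). Replicate 3 was thus the one that differed most in the order of its peaks.

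**Figure D1:**
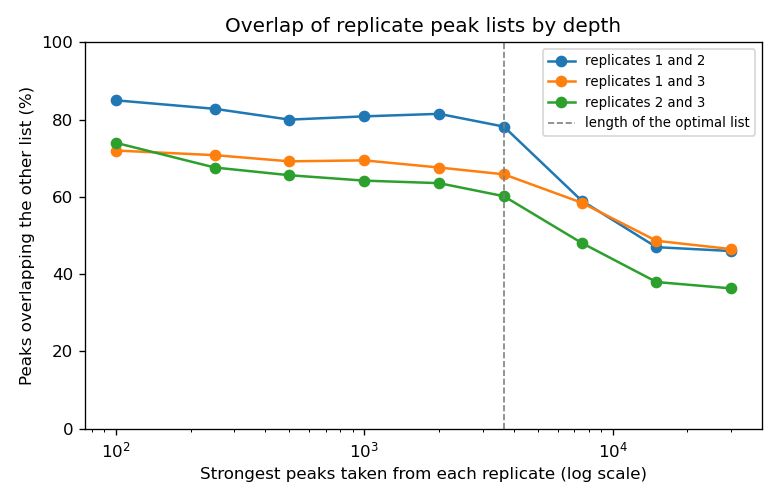
Percent of peaks that overlap the other replicate's list (vertical axis) against the number of strongest peaks taken from each replicate (horizontal axis, log scale), 1 line per pair of replicates. At 3646 peaks, the dashed line, the pairs stand at 78.2%, 65.8% and 60.2%, and with all 30000 peaks they stand at 46.0%, 46.5% and 36.3%.

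The next comparison asks where in genes the peaks lay. Promoters held 48.8% of the summits (1779 peaks, 95% interval 47.2 to 50.4), 3.59 times the 13.6% given by random placement. Coding sequence outside the promoter window was almost empty, with 10 summits (0.274%) against 13.1% by random placement, a fold of 0.0209. The other classes below were likewise counted outside that window. Summits were also fewer than random in 3' UTRs (0.713% against 5.09%), between genes (13.7% against 27.1%), in introns (35.1% against 39.5%) and in 5' UTRs outside the promoter window (0.466% against 0.778%). For the first 5 of these 6 classes the two-sided permutation p was 0.001998, the smallest that 1000 placements can give (adjusted 0.0028). For 5' UTRs the adjusted permutation p was 0.0303. The other exons held 0.878% against 0.809% (adjusted permutation p = 0.683).

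The median distance from a summit to the nearest TSS was 541 bp. The TSS-proximal share was 49.3%, 40.6% and 56.4% in the top lists of replicates 1, 2 and 3, a mean of 48.8% ± 7.90 (SD, n = 3), and each lay above the random share. The coding share was 0.411%, 1.34% and 0.384%. Pooled peaks below the optimal list differed, with 24.7% TSS-proximal and 19.0% in coding sequence. The intron deficit depended on the TSS window, since with 200 bp the fold was 1.00. In replicate 2's top list it was 0.979 (adjusted permutation p = 0.326).

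**Figure D2:**
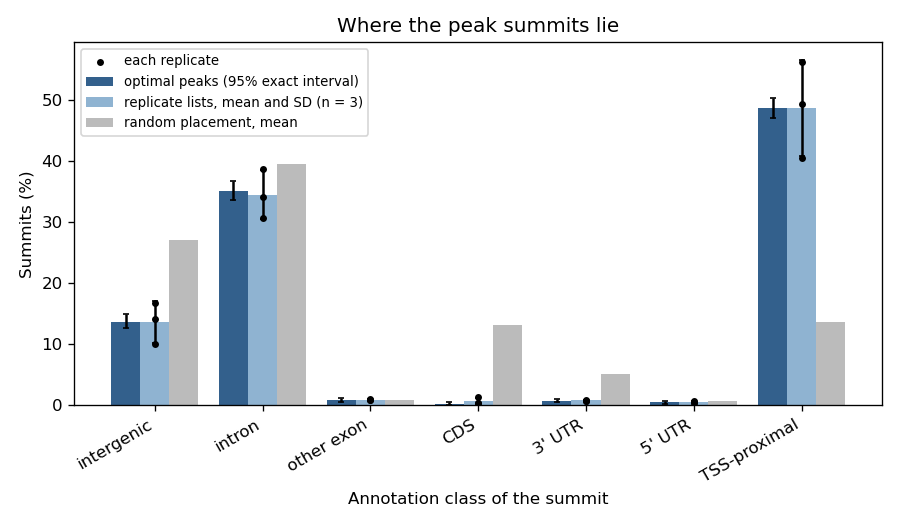
Percent of summits (vertical axis, from 0) in each annotation class, for the optimal peaks with 95% exact intervals, for the replicate top lists as mean and SD with each replicate as a point, and for random placement. The TSS-proximal bar of the optimal peaks stands at 48.8% and that of random placement at 13.6%. Coding sequence outside the TSS window stands at 0.274% against 13.1%.

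Peaks were spread over the arms nearly in proportion to sequence, except on the small chromosome 4. That chromosome, which is rich in heterochromatin, held 12 peaks, 9.01 per Mb and 0.330 times its share by length (exact binomial test, adjusted p = 3.23e-05). It was below its share by length in each of the 3 replicates. The X chromosome held 702 peaks, 29.9 per Mb and a fold of 1.10 (exact binomial test, adjusted p = 0.0238). Replicate 3 did not show that excess, with 17.0% of its top list on X, against 19.9% in each of the others and 17.6% of the sequence. Arm 2L held 694 peaks, a fold of 1.08 (exact binomial test, adjusted p = 0.0474), and no replicate's top list alone passed on this arm. The arms 2R, 3L and 3R had folds of 0.956, 0.952 and 0.974, with adjusted p from the exact test of 0.237, 0.206 and 0.394.

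Since Pointed binds DNA through an ETS domain, which recognises a GGAA core, the windows around summits were searched for ETS patterns. The pattern CMGGAAR was scarcer at peaks than in matched background. It was found in 205 windows (5.62%, 95% interval 4.90 to 6.42) against 8.31%, an odds ratio of 0.657 (0.544 to 0.793; Fisher's exact test, adjusted p = 3.26e-05). The replicate top lists gave 0.803, 0.812 and 0.754. The same letters reversed, a control of like composition, were scarcer still, at 3.46% against 6.66% and an odds ratio of 0.501 (Fisher's exact test, adjusted p = 3.57e-09). The narrow pattern ACCGGAAR had an odds ratio of 0.918 (0.558 to 1.51) and the core CCGGAA one of 0.800 (0.624 to 1.02), with adjusted p of 0.920 and 0.145 by Fisher's exact test. In the replicate top lists the narrow pattern had odds ratios of 1.2, 1.24 and 1.56. It occurred in 34 peak windows and 37 background windows, so its odds ratio is imprecise.

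The share of windows with CMGGAAR did not follow peak signal. It was 6.32% in the strongest decile and 5.21% in the weakest, between 4.11% and 6.87% in all 10, with Spearman's rho of 0.00178 across peaks (permutation p = 0.915).

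Of the other patterns, 4 were in excess and 1 was scarcer besides the control. The DRE, the site of the promoter factor DREF, was in 3.21% of windows against 1.07%, an odds ratio of 3.07 (2.11 to 4.54; Fisher's exact test, adjusted p = 3.32e-09). The replicate top lists gave 3.37, 1.51 and 5.32. Motif 1, bound by the promoter factor M1BP, had an odds ratio of 2.60 (1.5 to 4.69; Fisher's exact test, adjusted p = 9.53e-04), and 7.87, 2.65 and 5.28 in the replicates. GAGA repeats, bound by GAGA factor, had 1.78 (1.31 to 2.44; Fisher's exact test, adjusted p = 5.55e-04), and the E-box CAGCTG had 1.58 (1.32 to 1.89; Fisher's exact test, adjusted p = 1.79e-06). The Runx pattern was scarcer, at 0.726 (0.603 to 0.873; Fisher's exact test, adjusted p = 0.00143). Patterns for Zelda, AP-1, Grainyhead, homeodomains, TCF, Su(H), GATA factors and the E-box CACATG did not pass, with odds ratios from 0.801 to 1.33. Set against weaker pooled peaks, DRE had an odds ratio of 0.778 and motif 1 one of 0.775, so their excess was over background sequence and not over the weaker peaks. Against those peaks GAGA (1.19) and Runx (0.907) did not pass either, while CAGCTG had 1.2 (1.02 to 1.43; Fisher's exact test, unadjusted p = 0.0295, adjusted 0.149). CMGGAAR was scarcer than in those weaker peaks, at 0.748 (0.617 to 0.906), and so was its reversed control, at 0.681 (0.536 to 0.864). Both passed Fisher's exact test, with adjusted p of 0.0232 and 0.0226. The windows 2 kb to the right were not matched on class or GC, nor kept away from other peaks. Against them GAGA had 1.05 and CAGCTG 0.959, and neither passed Fisher's exact test. Away from TSSs none of the 4 patterns in excess passed. DRE had 0.453 (0.123 to 1.42) there and motif 1 had 1.5 (0.172 to 18). GAGA had 1.39 (0.872 to 2.24) and CAGCTG 1.31 (0.988 to 1.74). These intervals do not exclude an excess away from TSSs. Within 50 bp of summits GAGA had 1.44 and did not pass. In wider windows GAGA passed Fisher's exact test, with 2.42 (2.04 to 2.87) within 250 bp and 2.51 (2.21 to 2.87) within 500 bp. Motif 1 did not pass in the 1823 stronger peaks (1.59) or in those of all replicates (1.78). Its odds ratio rests on 49 peak and 19 background windows and is imprecise. It was 9.54 within 50 bp, 5.50 against windows 2 kb to the right and 3.41 with 10 background windows per peak. DRE had 5.43 and 5.46 under the first 2 of these, and Runx 0.483 within 50 bp. Within 250 bp Runx had 0.879 and did not pass.

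**Figure D3:**
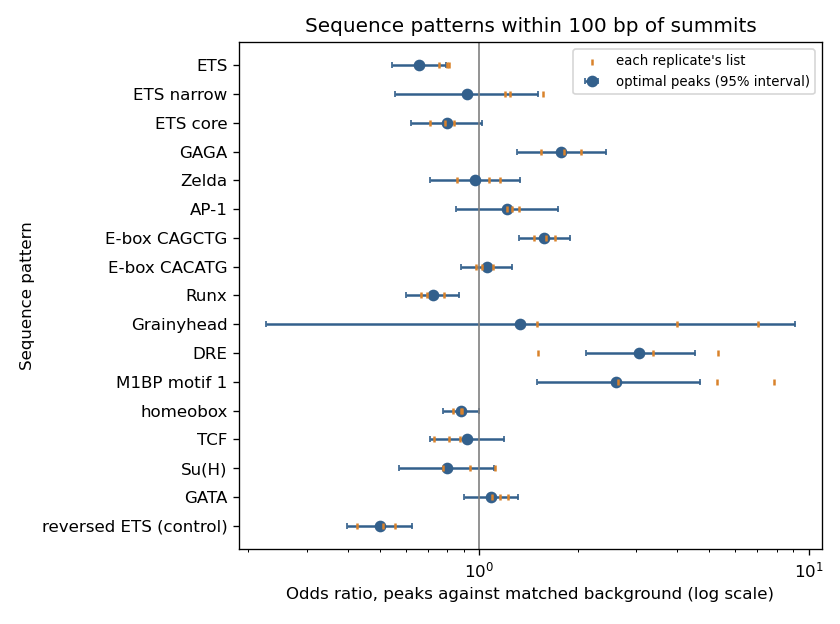
Odds ratio of each of 17 sequence patterns within 100 bp of summits, peaks against matched background (horizontal axis, log scale), with 95% intervals for the optimal peaks and ticks for each replicate's top list. CMGGAAR lies below 1 at 0.657 and its reversed control at 0.501, while DRE lies at 3.07.

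The last comparison on dm6 asks which groups of genes carried peaks. In all, 4103 of 13945 protein-coding genes (29.4%) had a summit in their span or within 2 kb. Peaks often lay near several genes, with 47.4% of them in or near at least 2, and 351 peaks were near none. Of the 19 lists, 2 passed the threshold and 5 had an unadjusted permutation p under 0.05.

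Genes of cytoplasmic ribosomal proteins carried more peaks than random genes of like span. Of 92 genes 48 were bound, against 20.2 ± 3.92 (SD over random lists) expected, a ratio of 2.37 (adjusted permutation p = 0.0019, from an unadjusted value that is the smallest 10000 lists can give). The top lists of the replicates bound 50, 31 and 57 of them. Among the bound members were RpL32 (rank 134, nearest to CG7943) and RpL34b (rank 200, 92 bp from its own TSS). RpL10, RpL10Aa and RpL10Ab had none. Genes of chemosensory receptors, most of which act in sensory neurons of larvae and adults, carried fewer, with 9 of 179 bound against 47.1 expected, a ratio of 0.191 (adjusted permutation p = 0.0019). The strongest of these, near Or85f, is the peak at RpL34b. Gr89a and Gr5a (nearest to the TSS of Tre1) followed, and Gr10a, Gr10b and Gr21a had none.

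Of the genes of EGFR ligands, receptor and feedback, 13 of 18 were bound, against 8.30 expected, a ratio of 1.57 (unadjusted permutation p = 0.0464, adjusted 0.176). The top lists of the replicates bound 12, 13 and 14. The count passed when peaks were given to the nearest TSS, at a ratio of 2.07 (adjusted permutation p = 0.0152). The strongest peaks were at aos, a secreted inhibitor of the receptor (3L:16480424-16480696, intron, signal 618, rank 125), at spi, which encodes the ligand Spitz (2L:19575640-19575867, TSS-proximal, signal 594, rank 137), and at S, which encodes the ligand chaperone Star (2L:1075841-1076065, intron, signal 490, rank 220). Cbl, grk and kek1 had no peak. Of the RTK-MAPK cassette 10 of 15 genes were bound, against 5.92 expected (adjusted permutation p = 0.186). With peaks given to the nearest TSS its ratio was 0.95, with 4 bound, and by Fisher's exact test, which does not match on span, it was 2.27 and passed (adjusted p = 0.00842). By that test the EGFR, Wg, Hh and Dpp, apoptosis, ecdysone and male accessory gland lists passed too. Its strongest peaks were at Shc (rank 15), Raf (rank 36) and cnk (rank 205, 300 bp from the TSS of l(2)k01209), and Sos, rl and sev had none. In the ETS family 3 of 8 were bound, against 3.72 expected (adjusted permutation p = 0.981). These were aop, which encodes the ETS repressor Yan (6 peaks, the strongest at rank 304), pnt and Eip74EF (nearest to the TSS of CycT), while Ets21C, Ets65A and Ets96B had none.

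Other signalling lists did not pass either. Of Wg, Hh and Dpp pathway genes 17 of 25 were bound, against 11.5 expected (unadjusted permutation p = 0.037, adjusted 0.176), led by Med (rank 52, 5 bp from the TSS of the neighbouring Mnat9), Mad (rank 118) and fz (rank 129, in an intron but nearest to the TSS of CG13482), while ci, en and hh had none. Replicate 3's top list alone bound 20 of them and passed (adjusted permutation p = 0.00633). Notch pathway genes had 9 of 17 bound, against 5.40 expected (adjusted permutation p = 0.219). Their strongest peaks were near E(spl)m8-HLH (rank 153, at the TSS of gro), N (rank 244, in an intron but nearest to the TSS of CG18508) and neur (rank 719), and Brd, E(spl)m2-BFM and E(spl)m4-BFM had none. With peaks given to the nearest TSS the Notch list passed, at a ratio of 2.37 (adjusted permutation p = 0.0294). The FGF and tracheal list had 9 of 17 bound, against 7.81 expected (adjusted permutation p = 0.928), with ths, grh and bs (nearest to the TSS of CG44812) strongest and btl, kni and knrl without a peak.

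No list of tissues or of patterning genes passed the threshold. Of glial, midline and neuroblast genes 9 of 20 were bound, against 7.35 expected (adjusted permutation p = 0.858), with moody (rank 101), elav (rank 114) and sim strongest and Gli, ac and ase without a peak. Mesoderm, heart and muscle genes had 10 of 24, against 9.49 (adjusted permutation p = 1), led by Mef2 (rank 24, nearest to the TSS of Pal1), kirre and Poxm, while Act57B, Doc3 and H15 had none. Segmentation genes had 4 of 17, against 5.45 (adjusted permutation p = 0.869), with bcd, slp1 and cad (nearest to the TSS of Pomp) bound first and Kr, en and eve without a peak. Hox genes had 4 of 8, against 4.26 (adjusted permutation p = 1), with Antp, Abd-B and pb (nearest to the TSS of Ccp84Aa) strongest and Dfd, Scr and Ubx without a peak. Hemocyte genes had 4 of 11, against 4.94 (adjusted permutation p = 0.949), and ush (the peak nearest to cbt), Hml and Pvr were strongest, while Col4a1, NimC1 and Pxn had none. Endoderm and gut genes had 5 of 8, against 3.40 (adjusted permutation p = 0.653), with bin, fkh and cad strongest and GATAe, mirr and srp without a peak.

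Among the remaining lists, apoptosis genes had 7 of 10 bound, against 3.21 expected (unadjusted permutation p = 0.0282, adjusted 0.176). The proapoptotic gene hid, a known target of EGFR signalling, had the strongest peak (rank 360), then Diap1 and Dark (76 bp from the TSS of RhoGEF2), and its neighbours grim, rpr and skl had none. Ecdysone response genes had 8 of 10, against 5.26 (adjusted permutation p = 0.301), with Hr3 (rank 106), EcR and br (nearest to the TSS of Mur2B) strongest and Eip93F and Kr-h1 without a peak. Cell cycle genes had 7 of 15, against 5.07 (adjusted permutation p = 0.653), with CycB (rank 31), fzr (rank 108, 340 bp from the TSS of CG3009) and E2f1 (106 bp from the TSS of InR) strongest and Cdk2, CycA and CycB3 without a peak. The list of eggshell and yolk proteins had 2 of 19, against 4.09 (adjusted permutation p = 0.653). These were Cp190, which is not an eggshell gene, and Yp3, whose peak was nearest to rdgB, while Cp110, Cp15 and Cp16 had none. The list of male accessory gland proteins had 2 of 47, against 6.08 (adjusted permutation p = 0.219). Both peaks, near Sfp26Ad and Sfp84E, were nearest to other genes (Gpdh1 and CD98hc), and Acp24A4 and Acp26Aa had none. Acp1, a cuticle protein gene taken in by its symbol, had none either.

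**Figure D4:**
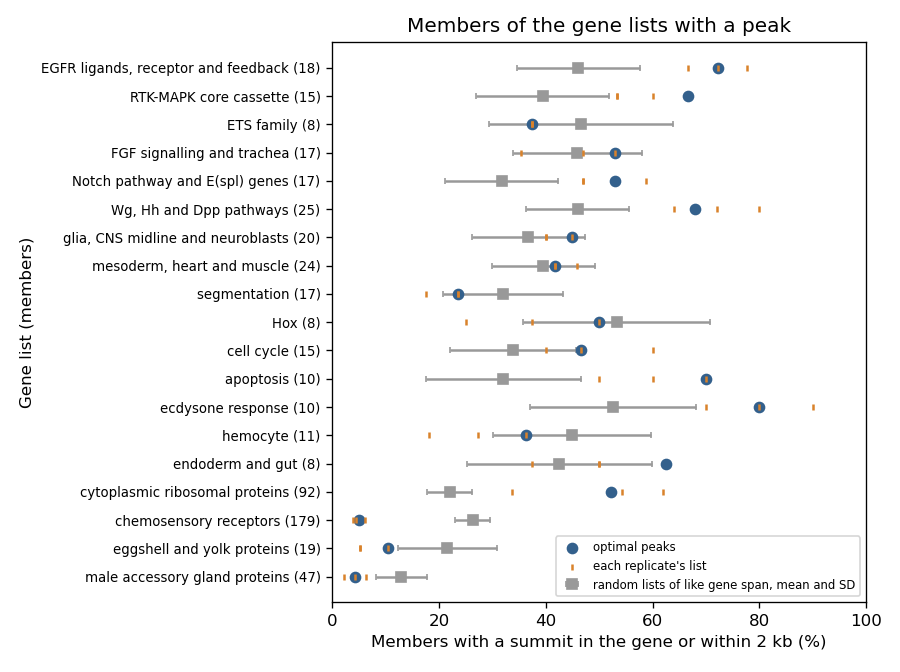
Percent of the members of each of 19 gene lists with a summit in the gene or within 2 kb (horizontal axis), for the optimal peaks and each replicate's top list, with the mean and SD of random lists of like gene span. Ribosomal protein genes stand at 52.2% and chemosensory receptors at 5.03%, the only lists past the threshold.

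The same libraries were also processed on build dm3. The optimal list there held 3543 peaks, against 3646 on dm6, and again these were exactly the peaks of highest signal in the pooled list. No arm's share of peaks on the 6 arms differed between builds by more than 0.171 percentage points. The median signal was 156.7 on dm3 and 153.5 on dm6. The highest signal differed, at 7844 on dm3 and 2989 on dm6.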

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

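Peaks left out of the comparisons were flagged when there were more than 3, a rule that is not a test. The dm3 optimal list held 7 peaks outside X, 2, 3 and 4. They entered the count and signal values given for that build but no arm share or other comparison. They stand out because 5 of them lie on Uextra, the dm3 collection of unplaced sequence, and include the strongest peak of the whole list. That peak (Uextra:26599228-26599695) had a signal of 7844, against 2989 for the strongest peak on the arms. Within the list of replicate 1 it had 7791, against at most 1245 on the arms. Within those of replicates 2 and 3 it had 33.3 and 20.7, against at most 1184 and 892 on the arms. The next 4 had signals of 3308, 1548, 828.5 and 258.2 in the optimal list. The last 3 of them had an overlapping peak in the relaxed list of replicate 1 and none in those of replicates 2 and 3. The scale of the signals is not stated in the sources used here, so they are not compared between lists. A dm3 sequence was not used here, so what these regions contain was not examined and no explanation was tested. The dm6 lists showed 0 optimal peaks outside the arms.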

How the results depend on the processing

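Alternatives with 10 background windows, weaker pooled peaks, windows of 500 bp, peaks by TSS class and peaks of all replicates were chosen after seeing the data. The TSS-proximal excess kept its direction and passed under every alternative run, with folds from 2.5 to 5.64. The midpoint alternative says little, since 7 peaks changed class. Unknown read depth limits every list. Unless given, the cause of a change was not tested.

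Mean replicate overlap was 70.7% with 50% reciprocal overlap and 97.7% with complete relaxed lists, which hold more peaks. Without 1 replicate it ranged from 77.5% to 84.1%, and mean rho from 0.533 to 0.806, the latter without replicate 3. The X fold was 0.970 in replicate 3's top list. The CMGGAAR odds ratio stayed below 1 throughout. It no longer passed for the narrow pattern (0.918), the core (0.800) or peaks of all replicates (0.777). With 10 windows per peak it was 0.694, the core passed at 0.705 and the narrow pattern stood at 1.15 (0.778 to 1.64). The rho of ETS match and signal was -0.00254 with 50 bp windows. The number of lists past the threshold was 4 with the nearest TSS and 8 by Fisher's exact test, which does not match on span.

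Among single classes and patterns, the intron fold became 1.00 with a 200 bp TSS window, CAGCTG became 0.959 against windows 2 kb to the right, DRE 0.778 and motif 1 0.775 against weaker peaks, and DRE 0.453 away from TSSs. Ratios of lists that did not pass crossed 1 in other cases. Within 1 kb of a TSS these were FGF 0.441, Wg, Hh and Dpp 0.762, glia 0.866, mesoderm 0.346, apoptosis 0.956, ecdysone 0.766, hemocyte 1.00 and gut 0.467. With the nearest TSS they were RTK-MAPK 0.95, segmentation 1.78, Hox 1.17 and hemocyte 1.35. By Fisher's exact test they were ETS family 1.27, Hox 1.70 and hemocyte 1.24. With peaks of all replicates they were FGF 0.932 and gut 0.886. FGF was 0.755 in replicate 3 and gut 0.914 in replicate 2. Of the other tested values for single classes, arms, patterns and lists, 195 kept direction and side of the threshold, 16 no longer passed and 9 newly passed. A further 26 had no test and moved by less than the spread between replicates or stayed in the 95% interval.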

Other observations

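Tests of the ETS pattern within 500 bp and in the 364 strongest peaks, the tests of words on held-out arms, in all peaks and away from TSSs, and the test of replicate 3 with a 1000 bp TSS window were chosen only after the result was seen. Peaks by TSS class, used for the ETS pattern away from TSSs, were likewise chosen after seeing the data. The words themselves were also found in these data.

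Short words that are none of the 17 patterns were in excess at the peaks. All words of 6 bases were compared between peaks on X, 2L and 2R and their matched background, and 158 of 2080 were in excess and 147 scarcer past an adjusted p of 0.05 by Fisher's exact test. The leading word was ACAGTG, in 22.4% of windows against 7.06%, then ACACTG, in 20.4% against 7.25%, and CAGTGC, in 18.9% against 7.74%. Of the 10 leading words, 7 contain CACTG or its reverse complement CAGTG. On the arms not used to choose the words, at least 1 of the 10 stood in 61.5% of peak windows against 38.7% of background, an odds ratio of 2.53 (2.19 to 2.93). Over all optimal peaks, which include those the words were chosen on, it was 2.83 (2.57 to 3.11). The top lists of replicates 1, 2 and 3, on all arms, gave 2.80, 2.91 and 2.28. The pentamer CACTG lay beside summits more than on them, at 4.23 per kb from 100 to 50 bp to the left and 4.19 per kb from 50 to 100 bp to the right. It stood at 2.81 and 3.26 per kb in the 50 bp either side of the summit and at 1.90 per kb from 500 to 450 bp to the left. GGAA, the ETS core, was less frequent near summits, at 7.19 per kb just left of them against 8.68 per kb at that distance. Both profiles are raw counts without a background or a control pattern. They do not separate either word from the base composition around summits.

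Chance choice of words, transposable elements and promoter sequence were weighed for this excess. All 10 leading words passed on the held-out arms 3L, 3R and 4, with an adjusted p by Fisher's exact test of 1.88e-06 for the weakest, which argues against chance. Most of the words overlap one another, so these are not 10 independent tests. The words were not set against weaker pooled peaks. Of peak windows with a leading word, 0.478% overlapped an annotated transposable element, below the 20% bound set beforehand. Of all optimal peak windows 0.658% did, 24 in number, so that bound could hardly be reached whatever the words. The values show only that annotated elements were rare at the peaks as a whole. In peaks of the held-out arms away from TSSs the odds ratio was 3.75 (3.04 to 4.64), which argues against promoter sequence as the whole source. A candidate explanation is that a DNA-binding factor other than Pointed marks many of these sites, a hypothesis raised by these data and not tested. No biological explanation was tested, and whether anti-GFP ChIP of other proteins gives the same words was not analysed here.

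The lack of an ETS excess over matched background was weighed against misplaced summits, promoter peaks and weak peaks. Within 500 bp of summits the odds ratio of CMGGAAR was 0.767 (0.696 to 0.844), and in peaks away from TSSs it was 0.693 (0.534 to 0.899), both intervals below the bound of 1.2 set for these tests. The reversed control had 0.597 (0.538 to 0.662) and 0.515 (0.378 to 0.698) there, lower than CMGGAAR, a difference that was not tested. No excess over the background is thus not a lack relative to this control. Because the control was itself scarcer than background, an ETS excess relative to it could stay under the bound. These tests therefore cannot decide whether misplaced summits or promoter peaks hide such an excess. Within 500 bp the intervals of CMGGAAR and the control did not overlap, while away from TSSs they did. In the 364 strongest peaks the odds ratio of CMGGAAR was 0.839 (0.515 to 1.31). A modest excess there cannot be told apart from none with so few peaks, and the control is not reported for them. Indirect binding through partner proteins, and sites that any immunoprecipitation gives, may contribute and stay open. No biological explanation was tested.

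Replicate 3 had more TSS-proximal peaks in its top list, 56.4% against 49.3% and 40.6%. With a TSS window of 1000 bp the shares were 66.7%, 59.4% and 51.6% in the same order, and the gap to the mean of the other 2 was 97.8% of that with 500 bp (bootstrap interval 87.3 to 109). This argues against summits moved from within 1000 bp of a TSS to within 500 bp, and longer moves stay open. It replaces a test on peaks shared by all replicates, which decides nothing because peaks that must overlap cannot have summits far apart. In the 1000 strongest peaks the shares were 56.2%, 50% and 57.2%, so that the gap was 36.0% of the full one (bootstrap interval 1.51 to 63.3). Lists reaching different depths may therefore account for part of it, but the interval spans the 50% bound and how much cannot be told apart. Of peaks found in 1 replicate's top list alone, 49.0%, 16.8% and 62.6% were TSS-proximal in replicates 1, 2 and 3, so replicate 2's low share belongs to the pattern too. Differences in embryo age within the collection window stay open and were not tested.

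The relaxed lists differed on chromosome 4, with 62 peaks in replicate 1, 33 in replicate 2 and 229 in replicate 3. The last is 0.763% of that list (95% interval 0.668 to 0.868), below the 0.996% of sequence that the chromosome holds.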
